A study of Mus musculus with 6 samples.

How the data were processed

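The samples were mouse immature dendritic cells grown from the bone marrow of 6-week-old male C57BL/6 mice, per the labels' protocols. Marrow cells were cultured in medium with 10% serum, GM-CSF at 20 ng/mL and interleukin-4 at 10 ng/mL, harvested on day 6 and enriched on magnetic beads for the integrin CD11c. The treated cells then received hydrogen peroxide (H2O2) at 100 µM for 24 h. RNA libraries were read on DNA nanoballs by combinatorial probe-anchor synthesis. GEO's labels put 3 samples in each group. The labels also do not say whether the samples of a group came from separate mice or cultures. The p-values therefore measure only the spread between these samples, which may be technical.

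The deposited values are estimated counts of reads per gene, not normalized, per the file headers and the values themselves: between 8.38% and 9.03% of the values in a library were not whole numbers. The submitters' processing notes name HISAT, Bowtie2 and the mouse build GRCm38.p6, without roles or versions. The read counter, the annotation release, the strand setting and any filter are not given in the sources used here. Antisense and overlapping genes, and gene families with near-identical copies, may therefore share reads. Each file held 17567 rows, identified by NCBI Gene numbers. Symbols and coordinates came from a RefSeq gene table of the same build, GRCm38.p6, which matched 17520 rows (99.73%). The 47 unmatched rows held 0.14% of the counts and kept their numbers. No row was mitochondrially encoded, so that list was not tested. A table of the whole series held the same values as the 6 sample files, with 0 differences in any column.

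The file of H2O2 replicate 3 equalled that of H2O2 replicate 1 in all 17567 values. The 2 were counted as 1 library, which left 5 distinct libraries, 3 control and 2 H2O2. No other pair agreed within sampling noise: chi-square per degree of freedom, over genes with at least 10 counts in the pair, was 5.07 for control replicates 2 and 3 and between 27.2 and 107 for the rest. The header of the copied column repeats the title of H2O2 replicate 1. This points to that sample as the owner of the values but does not settle it.

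Counts were rounded to whole numbers. Genes were kept by edgeR's filterByExpr (minimum count 10, minimum total 15), which left 12209 genes, and libraries were scaled with TMM factors. The planned test was edgeR's quasi-likelihood F test of H2O2 against control with no further term (3 residual degrees of freedom). Calls needed a Benjamini-Hochberg adjusted p of at most 0.05, and the series' own threshold of 1 was read as a log2 fold change. Standard errors were the absolute log2 fold change over the square root of F. The libraries fell into 2 sets by Y-linked transcripts (at least 100 counts over 4 genes in set A). A second fit with a term for the set (2 residual degrees of freedom) was therefore added after the data were seen. CPM values are counts scaled to the TMM-adjusted library size, given as mean ± SD. Those of the Y-linked genes and of the X-linked genes Eif2s3x and Kdm5c are scaled to the library total without TMM factors. The samples did not allow an exact permutation test below 0.1, the smallest p for 3 libraries against 2. Intervals across libraries cover the spread of these libraries and not other sources of error. The tools were R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.

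Before the data were examined, 36 gene lists were fixed, with 782 genes, of which 743 had a row (4 through an older symbol). The 31 lists with at least 5 tested genes were tested with limma's camera on log2 CPM (prior count 2) with the preset correlation of 0.01, and again with the correlation estimated per list and with fry. Named genes followed a rule fixed at the same time. It takes the 10 largest changes each way among called genes with a log2 change of at least 1, non-overlapping groups, a mean of at least 10 CPM and an established symbol. It adds, per list, the 2 called genes with the lowest p and the most abundant gene, and 19 genes given whatever their values. Further called genes of a list are named where 5 or fewer moved one way, which was decided after their values were seen. A gene that the rule takes is not reported here. In the fit with the set term, non-overlap was read within each set: H2O2 beyond every control library of its own set.

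The fits were tested on simulated data for the comparison of H2O2 with control. In 5 simulations of 12209 genes, 200 genes were changed by 1.5-, 2- or 4-fold. With the set term 63.8%, 80.4% and 96.8% of these were recovered, and 95 of 857 calls (11.1%) were false, above the nominal 5%. Without the term 0%, 0.4% and 44.8% were recovered, with 0 false calls among 113. The simulated means held the difference between the sets as fitted to the real counts, and the spread came from the fit with the term. The comparison of the fits therefore favours the term by construction and is no evidence for it. Camera called 0 of 155 list tests with the term and 1 of 155 without it. The simulated genes were independent, so this says nothing about lists of correlated genes.

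Settings chosen before the data were examined were DESeq2, limma-voom, DESeq2's size factors in edgeR, no filter, a filter at a mean of 5 CPM, the replicate number as a block, each library left out, and the series table. Pseudocounts, also chosen then, apply to normalized values only and were not used here. Added later were the set term with the same alternatives, and a fit of all 6 files as separate libraries. Simulation and all fits used fixed seeds.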

Results

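Transcript levels were measured in mouse immature dendritic cells, the antigen-sampling stage of a dendritic cell before maturation, kept as controls or exposed to 100 µM H2O2 for 24 h as a model of oxidative stress. Library totals lay between 16232604 and 16672491 estimated counts, so depth was nearly equal. The comparison covers 3 control libraries and 2 distinct H2O2 libraries, because the values of H2O2 replicate 3 were identical to those of H2O2 replicate 1. The libraries also split in a way that the treatment does not explain. Ddx3y, Eif2s3y, Kdm5d and Uty, genes of the Y chromosome, summed to 106 CPM in control replicate 1 and 96.4 CPM in H2O2 replicate 1. They summed to 0.12 CPM in control replicate 2, 0.308 CPM in control replicate 3 and 0.427 CPM in H2O2 replicate 2, although all mice were labelled male. Control replicate 1 and H2O2 replicate 1 are called set A below, and the other 3 libraries set B. The first principal component (66.0% of the variance) separated the sets and the second (22.9%) the treatment.

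**Figure D1:**
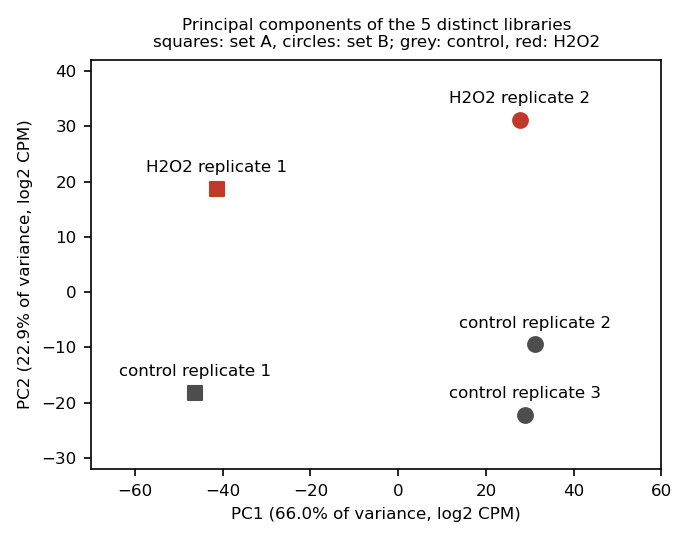
Principal components of log2 CPM for the 5 distinct libraries, with the first component on the horizontal axis and the second on the vertical axis, in log2 units. Both libraries of set A (squares) lie at the left and the 3 libraries of set B (circles) at the right, and the H2O2 libraries (red) lie above the controls (grey).

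The comparison of H2O2 with control asks which transcripts change under oxidative stress, and the series' design names metabolism and the cytoskeleton as its interest. Within the sets, targets of NRF2, the transcription factor of the antioxidant response, and metallothionein and iron genes were called upward as lists by camera, and cell cycle genes and mast cell and basophil markers downward. None of these lists held with a correlation between genes estimated from the data (adjusted p of at least 0.437). That version of camera has 2 degrees of freedom here, so it could hardly call any list and does not decide the matter. The estimates lay between -0.0182 (NRF2 targets) and 0.935 (cell cycle genes), against the preset 0.01. Hmox1, which degrades haem, rose 2.18-fold (log2 1.13 ± 0.086 SE; 208.2 ± 54.2 CPM, n = 3, to 485.6 ± 131 CPM, n = 2). Prdx1, a peroxide-scavenging peroxiredoxin, rose 2.21-fold (log2 1.15 ± 0.080; 1943 ± 197 to 4364 ± 94.7 CPM). Nusap1, a spindle protein, was 3.89-fold lower (log2 -1.96 ± 0.239; 40.7 ± 23.5 to 12.1 ± 6.92 CPM). EdgeR's quasi-likelihood fit called these 3 genes with a term for the set, a choice made after the data were seen, and with the planned replicate block, but not without either.

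With the set term, 480 genes were higher and 563 lower among 12209 tested, and 70 and 195 of them by at least 1 on the log2 scale. The planned edgeR fit without the term called 0 genes in either direction, with 853 genes at an unadjusted p under 0.05 and a smallest adjusted p of 0.39. Limma-voom without the term also called 0, and DESeq2 called 57 higher and 34 lower. The planned replicate block in edgeR, with 1 residual degree of freedom, called 220 higher and 334 lower, and 528 of these 554 were among the genes called with the set term. The block also parts the sets, because set A holds replicate 1 of each group. All 1043 genes called with the term changed the same way within set A and within set B. The fit assumes a common change in both sets and counts disagreement as spread. This agreement therefore follows largely from the call and is no replication. In 592 of them every H2O2 library lay beyond every control library, a separation found in 23.7% of all tested genes. Chance would give 20% only if all libraries were exchangeable. The sets differ and each group holds libraries of both, so that share is no baseline here. Of the 1043, 490 had an unadjusted p under 0.05 without the term. Across 12209 genes, which are not independent replicates, the log2 changes in set A and in set B correlated with r = 0.524. Without H2O2 replicate 2 only Mmp13 was called, without control replicate 3 the counts were 108 higher and 196 lower, and without control replicate 2 they were 254 and 468. Without H2O2 replicate 1 they were 1021 and 517, and without control replicate 1 they were 1248 and 816. With either library of set A left out, the set term absorbs the other one. Both of those fits therefore compare only H2O2 replicate 2 with control replicates 2 and 3, and hold no information from set A on the treatment. All values below are from the fit with the set term unless stated.

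**Figure D2:**
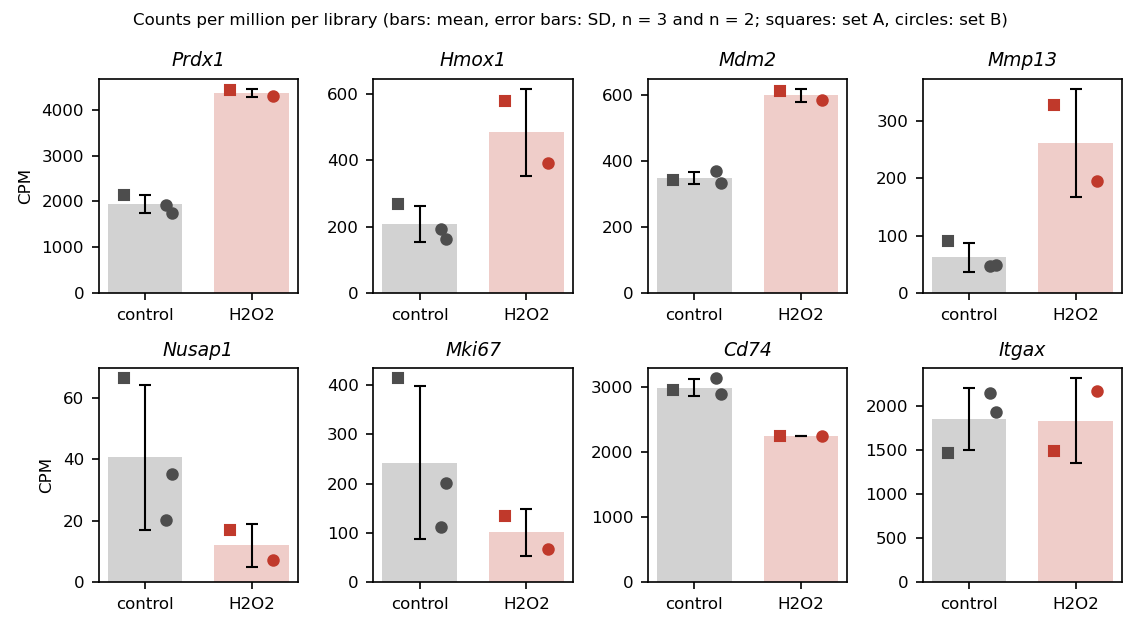
CPM (vertical axes, from 0) of 8 named genes in each library of the control (grey) and H2O2 (red) groups, with bars for the mean (n = 3 and n = 2) and error bars for the SD. Prdx1, Hmox1, Mdm2 and Mmp13 were higher and Nusap1, Mki67 and Cd74 lower in each H2O2 library than in the controls of its own set (squares, set A; circles, set B), while Itgax averaged 1856 CPM in control and 1837 CPM in H2O2.

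Of the 24 genes listed as NRF2 targets, 15 rose and none fell, and 21 rose when adjusted over the list alone. Their median log2 change was 0.546 (0.552 in set A and 0.464 in set B). Nqo1, a quinone reductase, rose 2.33-fold (log2 1.22 ± 0.088, adjusted p = 0.0044 by edgeR). Gclm, the modifier subunit of the enzyme that starts glutathione synthesis, rose by 0.87 ± 0.084 and Srxn1, which repairs oxidized peroxiredoxins, by 0.73 ± 0.066, both on the log2 scale. The ferritin heavy chain gene Fth1, the most abundant of the list, rose 1.48-fold from 6265 ± 1387 to 8681 ± 1464 CPM. Txnrd1 stood at log2 0.30 ± 0.077 with an adjusted p of 0.0587 by edgeR. Camera called the list upward (adjusted p = 1.03e-11), but not with an estimated correlation (adjusted p = 0.437). The same list was also higher in set A than in set B, by a median of 0.33.

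Metallothionein and iron genes rose in 8 of 14 cases and fell in none, with a median log2 change of 0.771; adjusted over the list alone, 9 rose. Mt1 rose 2.24-fold (log2 1.17 ± 0.108) and Mt2 2.58-fold (log2 1.37 ± 0.191), and the iron exporter Slc40a1 rose 2.78-fold, from 12.1 ± 4.42 to 34.2 ± 0.586 CPM. Mt1 and Mt2 are close relatives and may share reads. The list's adjusted p was 7.15e-06 by camera and 0.437 with an estimated correlation. Of 21 other peroxide and superoxide enzymes, Cat and Mgst1 (log2 0.49) rose and Sod3 fell. Adjusted over the list alone, 4 rose and 1 fell. Sod3 was scarce, with a mean of 1.292 CPM over the libraries and 0.06477 CPM in H2O2 replicate 2. Cat, which encodes catalase, rose 1.41-fold (log2 0.50 ± 0.071), and the most abundant gene, Gpx1, stood at -0.12 ± 0.065. That list was not called (adjusted p = 0.991), and neither were the 6 NADPH oxidase subunits (adjusted p = 0.821), with none rising or falling over all genes or adjusted over the list alone. Cybb stood at log2 0.20 ± 0.095.

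Targets of the stress-induced transcription factor p53 rose in 8 of 27 cases and fell in none, with 9 rising when adjusted over the list alone. Mdm2, the ubiquitin ligase that restrains p53, rose 1.72-fold (348.3 ± 18.9 to 599.8 ± 19.5 CPM; log2 0.78 ± 0.076). Ccng1 rose 1.66-fold (log2 0.73 ± 0.072). Cdkn1a, which encodes the cell cycle inhibitor p21, stood at log2 0.26 ± 0.156 (adjusted p = 0.327 by edgeR), with 0.66 in set A and -0.05 in set B. The list's median was 0.498 in set A and 0.136 in set B, and its adjusted p was 1.14e-04 by camera and 0.444 with an estimated correlation. Among 22 apoptosis regulators, Bcl2l1 rose by 0.34 ± 0.078 and Bmf, a pro-apoptotic gene, fell by 0.55 ± 0.070, the same counts as adjusted over the list alone. That list was not called (adjusted p = 0.821). Its most abundant gene, Mcl1, stood at 0.09 ± 0.082.

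Cell cycle genes fell in 27 of 32 cases and rose in none; adjusted over the list alone, 30 fell. The median log2 change was -1.24, with -1.30 in set A and -1.20 in set B. Named decreases among genes with a mean of at least 10 CPM included Ube2c (4.21-fold lower, log2 -2.07 ± 0.360), Kif11 (3.90-fold lower, -1.96 ± 0.291) and Aspm (3.94-fold lower, -1.98 ± 0.404), which act in mitosis. Ccnb2, Cdca3, Plk1, Kif14, Prr11 and Kif4 were between 3.52- and 3.84-fold lower. Mki67, a marker of proliferating cells, fell by 1.39 ± 0.243 and Aurkb by 1.26 ± 0.156 on the log2 scale. Camera called the list downward (adjusted p = 1.02e-14; 0.444 with an estimated correlation). The same genes were higher in set A than in set B by a median of 1.03. Mki67 varied widely among controls (242.4 ± 155 CPM), also within set B, at 111.7 and 201.5 CPM. The whole list did too. Summed over its genes, without TMM factors, it stood at 1028 and 1659 CPM in control replicates 2 and 3, against 657.9 CPM in H2O2 replicate 2. In set A it stood at 2855 CPM in control and 1273 CPM in H2O2. The size of the fall within set B therefore depends on the control library.

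Dendritic cell maturation genes fell in 10 of 24 cases and rose in none (13 fell adjusted over the list alone), with a median of -0.27. Fscn1, an actin-bundling protein of dendrites, fell by 0.67 ± 0.074, Cd83 by 0.51 ± 0.070 and the costimulatory gene Cd86 by 0.36 ± 0.072. The chemokine receptor gene Ccr7, which guides mature dendritic cells, stood at -0.25 ± 0.069 (adjusted p = 0.0736 by edgeR). Cd80 stood at -0.07 ± 0.081, Cd40 at -0.05 ± 0.124 and the most abundant gene, Ccl22, at -0.21 ± 0.084. The list had an adjusted p of 2.98e-06 by camera and 0.437 with an estimated correlation, and camera did not call it without the set term (adjusted p = 0.116). It was higher in set A than in set B by a median of 0.841. MHC class II presentation genes fell in 8 of 15 cases and rose in 1; adjusted over the list alone, 11 fell and 2 rose. The gene that rose was Marchf1, a ligase that removes MHC class II from the surface (log2 0.67). H2-DMb2 was 2.06-fold lower (50.4 ± 11.2 to 23.3 ± 11.9 CPM) and H2-Eb1 fell by 0.58 ± 0.077 on the log2 scale (425.8 ± 67.2 to 293.3 ± 31.3 CPM). H2-Ab1 fell by 0.50 ± 0.101 and Cd74, the invariant chain, by 0.41 ± 0.073 on the log2 scale. Camera gave this list an adjusted p of 5.47e-04, and 0.444 with an estimated correlation. The 17 MHC class I genes were not called (adjusted p = 0.334), none rose or fell over all genes or adjusted over the list alone, and B2m stood at 0.18 ± 0.070.

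Markers of other cell types were measured in the same fit. Conventional dendritic cell markers fell in 4 of 16 cases and rose in none (8 fell and 1 rose adjusted over the list alone), namely Irf8 by 0.45 ± 0.069, Dpp4 by 1.22 ± 0.197, Flt3 by 1.01 and Zbtb46 by 0.33. Their adjusted p was 0.00196 by camera and 0.437 with an estimated correlation. Itgax, the CD11c gene used for enrichment, stood at 0.06 ± 0.076 and Mgl2 at -0.20 ± 0.087. Mast cell and basophil markers fell in 5 of 8 cases, also adjusted over the list alone, with a median of -2.05. The basophil proteases Prss34 and Mcpt8 were 13.6-fold (15.1 ± 9.35 to 0.946 ± 0.586 CPM) and 10.5-fold lower (6.82 ± 4.75 to 0.498 ± 0.120 CPM). Fcer1a, Ms4a2 and Cpa3 fell by 2.77, 2.14 and 1.95. The list's adjusted p was 2.67e-05 by camera and 0.437 with an estimated correlation, and it was lower in set A than in set B (median -1.65). Of 13 neutrophil markers 3 fell and 1 rose (5 and 2 adjusted over the list alone). Camera did not call them with the set term (adjusted p = 0.214) but called them downward without it (adjusted p = 0.0191, and 0.624 with an estimated correlation). Mpo, a granule enzyme of early granulocytes, was 13.6-fold lower (6.41 ± 3.35 to 0.439 ± 0.203 CPM), Ctsg fell by 3.35 and Cxcr2 by 0.60 on the log2 scale, and Mmp8 rose 1.79-fold. Of 18 macrophage and monocyte markers 1 rose and 3 fell (9 and 4 adjusted over the list alone). Camera did not call them with the set term (adjusted p = 0.121) but called them upward without it (adjusted p = 0.0222, and 0.384 with an estimated correlation). Their median was 0.228 but their mean 0.0279. Cd68 rose by 0.40 ± 0.065, the complement genes C1qb and C1qc fell by 0.91 and 1.20, Fn1 fell by 0.44 ± 0.065, and Chil3, the most abundant, stood at 0.25 ± 0.078. Of 4 tested eosinophil markers 3 fell and 1 rose, as when adjusted over the list alone: Prg2 fell by 3.96, Epx fell by 2.73 and Siglecf fell by 0.60, and Ear6 rose by 1.71. Of 6 plasmacytoid dendritic cell markers, Spib fell by 1.73 ± 0.259 and Cox6a2 rose by 1.44 ± 0.340, also adjusted over the list alone. Both were scarce, with means of 2.235 and 0.9948 CPM. That list (adjusted p = 0.703 by camera) and 5 stromal and endothelial markers (adjusted p = 0.950) were not called. Runx2 stood at 0.03 ± 0.079 and Pecam1 at -0.11 ± 0.066, and no stromal or endothelial marker rose or fell over all genes or adjusted over the list alone. No call was made among 4 T and natural killer cell, 3 B cell and 1 erythroid marker; adjusted over the list alone, 1 of the 4 and 2 of the 3 fell.

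**Figure D3:**
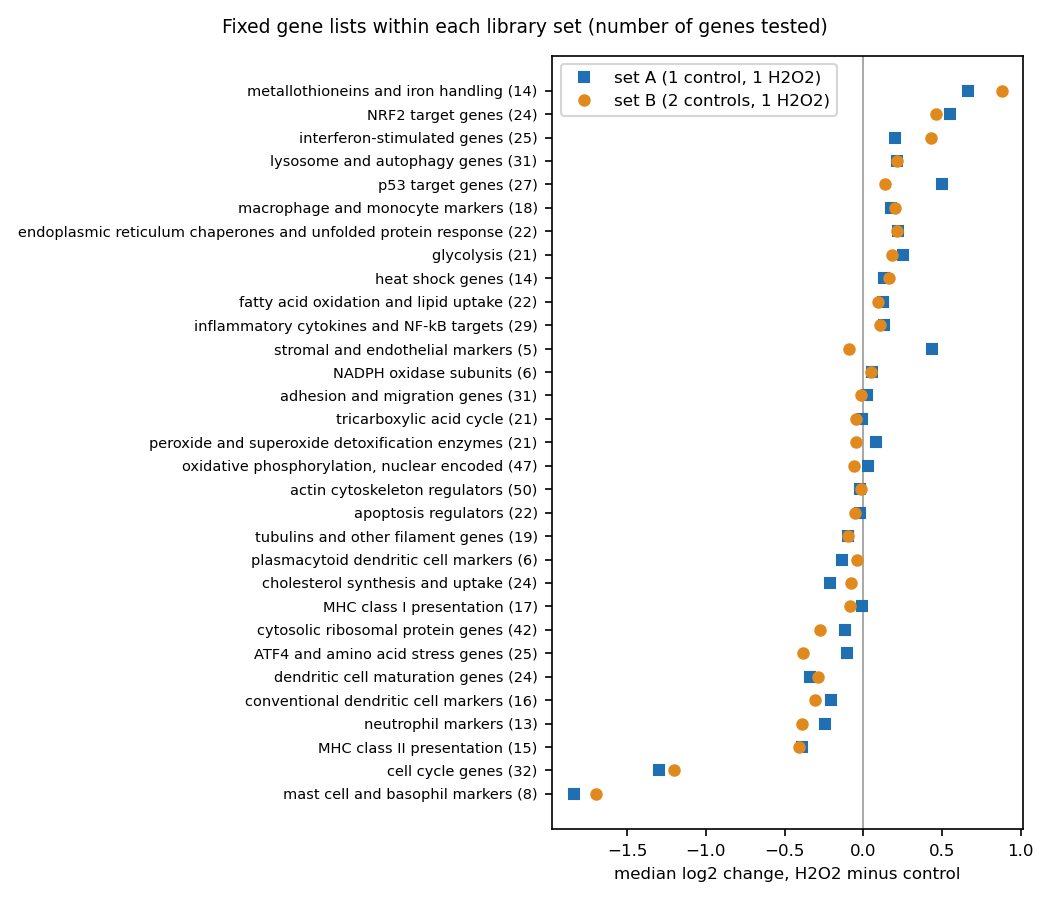
Median log2 change (horizontal axis, H2O2 minus control) of each fixed list with at least 5 tested genes, within set A (squares) and within set B (circles), with the number of genes in brackets on the vertical axis. Metallothionein and iron genes lie at 0.666 and 0.880, NRF2 targets at 0.552 and 0.464, cell cycle genes at -1.30 and -1.20, and mast cell and basophil markers at -1.84 and -1.70.

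For the cytoskeleton, 50 actin regulators gave 1 gene higher and 2 lower, also adjusted over the list alone, and camera did not call them (adjusted p = 0.394). Besides Fscn1, Vasp, which promotes actin filament growth, fell by 0.45 ± 0.073, and Tln1 (talin) rose by 0.30. Actb stood at -0.26 ± 0.087, Actg1 at -0.31 ± 0.078 and Cfl1 at -0.04 ± 0.068, none of them called. Tubulin and filament genes fell in 4 of 19 cases and rose in 2 (5 and 2 adjusted over the list alone; adjusted p = 0.0646 by camera, and without the set term 0.0268, or 0.355 with an estimated correlation). Stmn1, which destabilizes microtubules and marks dividing cells, fell by 1.48 ± 0.208, Lmnb1 by 1.16, Tubb5 by 0.70 and Tuba1b by 0.49. Tubb2a rose by 0.62 ± 0.075 and Lmna by 0.52, and Vim stood at -0.06 ± 0.068. Of 31 adhesion and migration genes 4 rose and 2 fell (6 and 4 adjusted over the list alone; adjusted p = 0.634 by camera). The collagenase gene Mmp13 (chromosome 9, 7272514 to 7283333, GRCm38.p6) showed the largest named increase, 3.87-fold, from 62.2 ± 25.1 to 261.8 ± 94.9 CPM (log2 1.95 ± 0.074, adjusted p = 4.47e-04 by edgeR). Mmp12, a macrophage elastase, rose 1.40-fold Mmp19 by 0.58 and Ccr1 by 0.36 on the log2 scale, and the integrin genes Itgal and Itgb7 fell by 0.41 ± 0.067 and 0.85.

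For metabolism, glycolytic genes rose in 7 of 21 cases and fell in 1 (11 and 2 adjusted over the list alone), with adjusted p = 0.0123 by camera, 0.444 with an estimated correlation and 0.0552 without the set term. Pkm rose 1.39-fold (886.7 ± 35.1 to 1239 ± 0.553 CPM) and Hk3 1.39-fold, the glucose transporter gene Slc2a3 fell by 0.98, and Hk2 stood at 0.24 ± 0.071 with Gapdh at 0.12 ± 0.066. Fatty acid oxidation and lipid uptake genes rose in 4 of 22 cases and fell in none (5 rose adjusted over the list alone; adjusted p = 0.0136 by camera and 0.437 with an estimated correlation). Plin2, a lipid droplet coat protein, rose 2.01-fold (184.0 ± 8.41 to 377.2 ± 37.1 CPM) and the scavenger receptor gene Cd36 1.80-fold. Angptl4 rose by 1.24 and Cpt1a, which admits fatty acids to mitochondria, by 0.50. Lpl stood at 0.22 ± 0.081. Cholesterol genes fell in 2 of 24 cases and rose in none (4 fell adjusted over the list alone), Pmvk by 0.67 ± 0.105 and Cyp51 by 0.47 ± 0.105, while Idi1 stood at -0.03 ± 0.154. That list had an adjusted p of 0.0197 by camera, 0.444 with an estimated correlation and 0.105 without the set term. None of 47 nuclear-encoded oxidative phosphorylation genes was called over all genes or adjusted over the list alone (adjusted p = 0.823 by camera), and Atp5b stood at -0.08 ± 0.067. Of 21 tricarboxylic acid cycle genes only Fh1 fell, by 0.38 ± 0.084, and none did when adjusted over the list alone (adjusted p = 0.346 by camera); Cs stood at -0.21 ± 0.065.

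Among stress and protein homeostasis lists, genes of ATF4 and amino acid stress fell in 10 of 25 cases and rose in 3 (14 and 3 adjusted over the list alone). The amino acid transporter gene Slc7a5 fell by 1.36 ± 0.074 and Shmt2, of serine and folate metabolism, by 1.18 ± 0.083, while Slc7a11, which imports cystine and is also an NRF2 target, rose 1.44-fold. Atf3 rose by 0.61 and Cebpb by 0.38. The median was -0.105 in set A and -0.382 in set B, with adjusted p = 1.14e-04 by camera and 0.444 with an estimated correlation. Endoplasmic reticulum chaperones rose in 7 of 22 cases and fell in 1 (14 and 1 adjusted over the list alone; adjusted p = 1.14e-04, and 0.437 with an estimated correlation). Hspa5 rose 1.44-fold, Calr by 0.37 ± 0.069 on the log2 scale and Manf 1.34-fold, and Herpud1 fell by 0.33. Heat shock genes rose in 2 of 14 cases and fell in none (3 rose adjusted over the list alone; adjusted p = 0.0197, and 0.437 with an estimated correlation). Hsph1 rose 1.30-fold and Hsp90aa1 1.29-fold, and Hspa8 stood at -0.14 ± 0.069. Lysosome and autophagy genes rose in 11 of 31 cases and fell in none (16 rose and 1 fell adjusted over the list alone; adjusted p = 2.30e-06, and 0.444 with an estimated correlation). Gpnmb, a glycoprotein of lysosome-rich phagocytes, rose 1.98-fold (2245 ± 242 to 4478 ± 4.90 CPM), the lysosomal lipase gene Lipa 1.46-fold and the protease gene Ctsd 1.37-fold. Ribosomal protein genes gave 1 lower of 42 (14 adjusted over the list alone), Rpl3 by 0.49 ± 0.096, with Rplp0 at -0.09 ± 0.070. Their adjusted p was 1.92e-08 by camera and 0.515 with an estimated correlation.

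Inflammatory genes rose in 5 of 29 cases and fell in none (7 rose and 1 fell adjusted over the list alone; adjusted p = 0.0598 by camera). The neutrophil-attracting chemokine gene Cxcl3 rose 2.05-fold (202.7 ± 14.2 to 420.2 ± 38.0 CPM) and Ccl2 1.39-fold, Nos2 rose by 0.65, Cxcl2 by 0.62 and Il1rn by 0.44, and Ccl6 stood at 0.08 ± 0.076. Interferon-stimulated genes rose in 1 of 25 cases, also adjusted over the list alone. This was Oas1a, by 0.49 ± 0.086. That list had an adjusted p of 0.0136 by camera and 0.792 with an estimated correlation, and it was higher in set A than in set B by a median of 1.02. The other named increases were Cyp26b1, which degrades retinoic acid (3.56-fold), Tm4sf19 (2.82-fold), the ubiquitin ligase gene Rnf128 (2.81-fold; log2 0.893 in set A and 1.947 in set B), Ppbp (2.63-fold), Hilpda, a lipid droplet protein (2.51-fold), and the Notch ligand gene Jag1 (2.33-fold). Cyp26b1 rested on low and uneven levels (9.87 ± 6.68 CPM in control and 30.7 ± 35.8 CPM in H2O2). Of the 31 lists tested, camera called 17 in each fit, 9 upward and 8 downward. None held with an estimated correlation in either fit, a version with too few degrees of freedom here to call a list readily. Fry, which asks whether a list's genes move on balance one way, called 0 without the set term and 4 with it: NRF2 targets, fatty acid oxidation, dendritic cell maturation and plasmacytoid dendritic cell markers. In the last of these, 3 of 6 genes were higher and 3 lower within both sets, so no common direction was seen.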

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

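Of the tests in this part, the counts for the library sets were chosen after the results were seen, as was the interaction of set and treatment. The direction check in set A and the count over other assignments were set out before their results. Gm13212 and Zfp991 changed differently after H2O2 in the 2 library sets by an interaction term in edgeR (adjusted p = 0.0305 for both). That fit has 1 residual degree of freedom, since 3 of the 4 groups by set and treatment hold 1 library, so its spread comes from control replicates 2 and 3 and from pooling across genes, and the difference rests on H2O2 replicate 2 alone. The change in set A minus that in set B was -1.54 ± 0.104 (log2 ± SE) for Gm13212 and -1.34 ± 0.0995 for Zfp991. Gm13212 stood at 98.6, 83.6 and 87.1 CPM in the 3 controls, 84.2 CPM in H2O2 replicate 1 and 211.7 CPM in H2O2 replicate 2. Zfp991 stood between 137.5 and 142.0 CPM in 4 libraries and at 359.2 CPM in H2O2 replicate 2. Both lie on chromosome 4 (145585172 to 145625343 and 147132093 to 147180579, GRCm38.p6) and belong to a zinc finger family with close copies, which may share reads, and no explanation was tested for them.

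The absence of calls in edgeR without the set term or the replicate block was weighed against 3 explanations, and none of them was settled. Splitting the 5 libraries by set called 2059 genes without a further term, and each of the other 9 of the 10 splits into 2 and 3 libraries, the treatment included, called 0. This points to a structure of the samples. The sets were found from the same counts and the first principal component already parts them, so the count restates their difference and does not test whether it hid the treatment. An effect in set B alone stays open. Of 2001 genes called within set B (1 H2O2 library against 2 controls) and measured in set A, 78.2% changed the same way in set A, where 65.5% of all tested genes did. That share passed the bound set beforehand for excluding it, but the bound took the genes as independent. The fit within set B has 1 residual degree of freedom and set A holds 1 library per group, so many genes may agree together by chance. Assigning the treatment to other libraries within the sets gave at most 0 called genes in the other 5 of 6 assignments, and the real one, the 1 with that many, gave 1043, but 6 assignments are too few for a share under 0.05.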

How the results depend on the processing

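The fit with the set term, its alternatives and the fit of 6 files were chosen after the data were seen; the others were planned. Without the term, DESeq2 called 57 higher and 34 lower (21 and 16 by at least 1 log2), the replicate block 220 and 334 (47 and 154), the set term 480 and 563 (70 and 195), and 6 files as separate libraries 5 and 2 (4 and 2). The other scaling, filters, voom and every left-out library kept 0. Lists called, 17, became 0 with an estimated correlation and with fry and 10 under the stricter filter. With the set term, no filter called 60 higher and 42 lower (22 and 16 by at least 1 log2), and these 102 were all among the 1043; the cause was not tested. Omitting the term gave 0 of each (0 and 0), the replicate block 220 and 334 (47 higher by at least 1 log2), 6 files 1320 and 1500, and the stricter filter 37 higher by at least 1 log2. Leaving out one library gave 1 to 1248 higher and 0 to 816 lower (1 to 150 and 0 to 225 by at least 1 log2), and 12 to 20 lists. The lowest counts were without H2O2 replicate 2, and the cause was not tested. Each fit that left out a library has 1 residual degree of freedom, so this limit does not set that fit apart. Leaving out H2O2 replicate 1 instead brought no such loss, but the 2 fits compare unlike libraries. Without H2O2 replicate 2 the change comes from 1 control and 1 H2O2 library of set A. Without H2O2 replicate 1 it comes from H2O2 replicate 2 and 2 controls of set B. The calls thus depended on including H2O2 replicate 2, but the counts do not tell its own weight from this difference in design. Lists called became 0 with an estimated correlation and 4 with fry. The replicate numbers pair only 2 distinct H2O2 libraries (correlations of deviations 0.81 and 0.714, mirrored by construction), so the block is a setting and not the design; 528 of its 554 calls were among the 1043. All 1043 kept their direction under each alternative that included the set or the block and measured them, and 1041 did without the term. These alternatives use the same libraries, so this is no independent check. Of 106 named genes, 78 were called, 77 of which were lost without H2O2 replicate 2 and 48 without a filter. The planned replicate block lost 15 of the 78. Leaving out control replicate 3 lost 26, control replicate 2 lost 12 and control replicate 1 lost 3. No called gene among these 106 changed sign, and the further genes named in the lists were not followed singly. Uncalled ones did: Cdkn1a (-0.0089 without the term; -0.057 to 0.66 leaving out a library), Idi1 (0.012; -0.44 to 0.27), Cd40 (0.067; -0.19 to 0.070), Ccl6 (-0.15), Itgax (-0.015) and Ccr7 (0.069) without the term, and Cybb (-0.010 to 0.36), Mcl1 (-0.068 to 0.21) and Cfl1 (-0.084 to 0.015) leaving out a library. Without the term, where none of 46 named genes was called, 18 changed sign in at least 1 setting. Library totals were nearly equal, with between 14419 and 15059 genes above 0 per library, and any limit set by depth was not tested.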

Other observations

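All tests in this part were chosen after the results were seen. The 2 library sets differed more than the treatment did: 2332 genes were higher and 2067 lower in set A with treatment as a term in edgeR. Among abundant genes, Apol7c was 13.3-fold (log2 3.73 ± 0.091), Clu 12.8-fold and Igf1 9.75-fold higher in set A. Ccn3 was 90.5-fold (log2 -6.50 ± 0.122), Car4 28.1-fold and the chemokine gene Ccl3 10.9-fold lower. Interferon-stimulated genes were higher in set A in 16 of 25 cases and lower in none, and dendritic cell maturation genes in 18 of 24 cases, with 4 lower. Neutrophil markers were lower in set A in 10 of 13 cases (median -1.63). With an estimated correlation, no list passed (adjusted p = 0.785 for these 3). That version has 2 degrees of freedom here too, so it could hardly call a list. Of the 1043 genes called for H2O2, 668 (64.0%) were also called between the sets, against 36.0% of all tested genes. Both calls share the same fit and spread, and the tested genes were not matched for abundance or spread. The excess therefore does not show a link between treatment and set. The X-linked gene Eif2s3x stood at 346 and 347 CPM in set A and between 401 and 427 CPM in set B, while Kdm5c lay between 166 and 176 CPM in all 5 libraries.

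Other zinc finger genes stood higher in H2O2 replicate 2 than in the other 4 libraries: Zfp984 at 180.1 CPM against at most 87.6, Zfp992 at 214.3 against at most 104.9, Zfp942 at 52.98 against at most 25.6 and Zfp935 at 67.5 against at most 37.8 CPM. They were picked by eye for their family, for which no enrichment was tested. Their interaction missed the threshold in edgeR (adjusted p = 0.054), as did that of genes outside the family at the same adjusted p, such as Igf1 (set A minus set B -1.20 ± 0.113) and Rnf128 (-1.06 ± 0.103).

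After H2O2, 27 of 32 cell cycle genes and 5 of 8 mast cell and basophil markers were lower, but neither list held with an estimated correlation (adjusted p of 0.444 and 0.437). A wrong scaling factor for a library would shift all genes alike, which argues against it as the whole cause. The median of the 32 cell cycle genes differed from that of 7592 other genes in the same range of abundance by -1.26 (log2; quartiles -1.70 and -0.787 against -0.113 and 0.155). The median of the 8 mast cell and basophil markers differed from that of 2848 such genes by -1.99 (quartiles -2.93 and -0.673 against -0.357 and 0.206). In both lists the upper quartile lay below the lower quartile of the other genes within set A and within set B too. A candidate explanation is that fewer dividing precursors, basophils and early granulocytes remained in the treated cultures, although the cells had been enriched for CD11c before H2O2 was added. It cannot be told apart from lower transcript levels per cell, because total RNA per library holds no cell numbers (median -2.05 for mast cell and basophil markers). The treatment itself is the design's biological explanation and stays open.

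Of MHC class II genes 8 of 15 fell and 1 rose. There were decreases in 10 of 24 dendritic cell maturation genes and 4 of 16 conventional dendritic cell markers, and 11 of 31 lysosome and autophagy genes rose. None of these lists held with an estimated correlation (adjusted p of 0.437 or 0.444). A lower share of dendritic cells would raise the markers of other cell types together. Mast cell and basophil markers (mean -1.95, 8 genes) lay below macrophage and monocyte markers (mean 0.0279, 18 genes), with an exact two-sided permutation p of 4.16e-05 across genes, which are not independent replicates. The markers of these other cell types therefore did not rise together. The comparison was chosen after the fall of the mast cell and basophil list was seen, so it cannot decide the question. A lower share of dendritic cells against macrophages stays open. Itgax, the CD11c gene used for enrichment, stood at 0.06 ± 0.076. A change in the macrophage and monocyte genes stays open, since their median was 0.228, 13 of the 18 were higher in both sets, and camera called them upward without the set term (adjusted p = 0.0222, but 0.384 with an estimated correlation) and not with it (0.121). A change of state within the CD11c-enriched cells remains a hypothesis and was not tested.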
